A study of Homo sapiens with 4 samples.

How the data were processed

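SCC12 cells, an established line of human skin squamous carcinoma, were profiled on 4 oligonucleotide arrays. Per the labels' protocols, the tumour cells were layered on a gel that held head and neck carcinoma-associated fibroblasts (CAFs), and the tumour cells that had not invaded were taken for RNA. The comparison cells were SCC12 never in contact with CAFs, and the labels do not say whether these also grew on a gel. Each group had 2 arrays. Per the labels' protocols, RNA was amplified and labelled with biotin. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

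The deposited values are MAS5 signal intensities on a linear scale, per the submitters' processing notes, which give no version. On every array the mean signal after trimming 2% at each end was 100, so the authors' values had been scaled globally. The array held 54675 probe sets. The platform's annotation gave 41097 probe sets 1 gene symbol, 1801 several and 11777 none, and 41043 of the first were matched to a current symbol. Probe sets with several symbols or none are unnamed here. No genome build was given in the sources used here, so no coordinates are printed.

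The 62 control probe sets were left out. The 29 signals at 0 were set to the lowest positive value, 0.1, and log2 was taken without further normalization. Probe sets with a mean log2 over the 4 arrays at or above the 40th percentile, a signal of 13.5, were kept, which left 32768 probe sets and 12525 named genes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, 2 residual and 7.88 prior degrees of freedom), and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A gene was represented by its kept probe set of highest mean. Tests are 2-sided.

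The 32 gene lists (595 genes, 547 of them named on the array) were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, where at least 5 members were measured. The lists were fibroblast, endothelial, leukocyte, melanocyte and basal keratinocyte markers, keratinocyte differentiation, interferon response, antigen presentation, inflammatory NF-kB targets, STAT3 targets, TGF-beta targets, epithelial adhesion, mesenchymal transition, matrix proteases and inhibitors, integrins and laminins, YAP targets, MAPK feedback and immediate early genes, EGFR ligands and growth factors, S phase and replication, mitosis, p53 targets, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, unfolded protein and amino acid response, NRF2 targets, heat shock, metallothioneins, Notch and Wnt targets, oxidative phosphorylation and ribosomal proteins. The other list was tested and counts in the adjustment over the lists, but is not reported here.

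The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes per direction with the largest change past the threshold, with groups that did not overlap and a higher mean at or above the median of the kept probe sets. Places left were filled by the smallest unadjusted p, and such genes are said not to pass. Up to 4 members of smallest p were added from each list described. Any other gene named was chosen after its values were seen.

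Alternatives covered the scaling between arrays, a constant added before the logarithm, the dim filter, the variance model, the replicate number as a block, each array left out, the threshold, the probe set per gene and the list test. Some were chosen after seeing the data. These are a dim filter on the mean linear signal, camera with an intensity trend of the variances, and the lower bound of a fold. The bound applies where both SCC12 only signals lay at or below 13.4, the highest signal on the 4 arrays of 27 bacterial control probe sets that stay near 0; that common level replaced a level for each array. Camera with the intensity trend had first served as the list test and was replaced by camera's default, the plain reading of the fixed design, which called fewer lists. A table of 36 combinations of scaling, constant and filter was also counted, with and without the block, before the fixed design was run; the design was not changed by it.

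The fit was tested on simulated data, with 200 of 32768 probe sets changed in 20 simulations of 2 arrays against 2. With variances drawn from limma's own model, 3.1% of log2 changes of 1, 45.3% of 2, 72.9% of 3 and 82.1% of 4 were recovered, and 5.29% of the calls were false. With each probe set's own moderated variance the shares were 18.9%, 72.4%, 88.2% and 93.3%, and 10.6% of the calls were false, above the nominal level. A simulated list of 25 genes without a shift had an unadjusted camera p under 0.05 in 10% of the 20 simulations under the first kind of variance. Under the second kind it was 0%. Genes were drawn independently, so false list calls from correlated genes were not simulated. Arrays were also drawn independently, so the correlation of 0.293 between deviations of same-numbered arrays, given below, was not simulated either. The estimated correlation between members in the data was 0.602 for the interferon list, 0.579 for mitosis and 0.622 for ribosomal proteins. The number of arrays limits the precision.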

Results

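Gene expression was measured in SCC12 squamous carcinoma cells that had been cultured on a gel with CAFs and had not invaded it, and in SCC12 cells never exposed to CAFs, with 2 arrays per group. Median signals were 22.6 and 25.5 on the exposed arrays and 21.9 and 30.3 on the SCC12 only arrays. Across the 32768 tested probe sets, log2 signals correlated at r = 0.955 between the exposed arrays and at r = 0.939 between the SCC12 only arrays. Between groups, r was 0.944 and 0.941 for arrays of the same number and 0.933 and 0.925 for the others, so each SCC12 only array correlated better with the exposed array of its number than with the other SCC12 only array. These correlations are across probe sets, which are not independent replicates.

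The comparison sets tumour cells that stayed on a gel with CAFs against SCC12 cells without CAFs, of which the labels do not say whether they also grew on a gel. Signals of COL1A1, COL1A2, COL3A1, COL6A3 and DCN, all on the fibroblast list, rose in the RNA of the exposed samples. COL3A1, a fibrillar collagen, had a signal of 601 ± 366 (SD, n = 2) in exposed cells and 3.7 ± 2.4 (SD, n = 2) in SCC12 only. It was at least 40.5-fold higher, and at least 27.3-fold and 27.5-fold on its other kept probe sets. Its adjusted p in limma was 0.00151. COL6A3, a chain of the microfibrillar collagen VI, was at least 15.3-fold higher (207 ± 41.1 against 3.65 ± 3.32, adjusted p = 0.0205), a call lost with quantile normalization (0.0748). COL1A1, a chain of collagen I, rose by 2.88 ± 0.22 on the log2 scale (SE), from 117 to 864, with an adjusted p of 0.00151. In SCC12 only cells, COL3A1 and COL6A3 lay at the level of bacterial control probe sets, so the folds are lower bounds.

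Among transcripts outside the fibroblast list, AKR1C2, an aldo-keto reductase of steroid metabolism, rose 10.2-fold, from 26.9 ± 4.24 to 275 ± 40.8 (SD, n = 2, adjusted p = 0.00497). CLCA2, an epithelial membrane protein, rose 7.72-fold, from 54.2 to 418 (adjusted p = 0.0114). NREP rose 4.14-fold, from 88.1 to 369 (adjusted p = 0.0435), a call lost with quantile normalization (0.0556), with the 60th percentile filter (0.0731), with the mean over its probe sets (0.259) and without SCC12 only replicate 1 (0.0618). The smallest p belonged to a probe set without a gene name here, which rose 14.8-fold, from 87.0 ± 6.15 to 1291 ± 153 (SD, n = 2, adjusted p = 0.000339).

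In all, 13 probe sets were higher in exposed cells and 0 were lower at an adjusted p under 0.05 in limma, while 1483 were higher and 1488 lower at an unadjusted p under 0.05. The 13 probe sets stand for 8 named genes and 1 unnamed probe set, and 5 of the 8 genes, COL1A1, COL1A2, COL3A1, COL6A3 and DCN, were on the fibroblast list. The groups did not overlap in 39.0% of tested probe sets, where chance gives 33.3%. With median centring 70 probe sets were higher and 1 lower. Both counts were far larger with the replicate number as a block, as given below. Calls stated here without a setting are those of the main fit. Without the intensity trend in the variance model 0 probe sets were called. With the mean over a gene's probe sets COL6A3, AKR1C2, CLCA2, COL1A1 and NREP did not pass (adjusted p from 0.136 to 0.259). The variances were fitted anew on the averaged genes there, and the log2 difference of COL6A3 stayed at 6.2. Those of AKR1C2 (3.57) and CLCA2 (3.05) were larger than in the main fit, and those of COL1A1 (2.18) and NREP (1.31) smaller. Leaving out exposed replicate 1, exposed replicate 2, SCC12 only replicate 1 or SCC12 only replicate 2 gave 137, 76, 39 and 129 higher and 103, 36, 3 and 49 lower probe sets.

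The other higher genes named by the rule did not pass in the main fit. Without the dim filter COL1A2 (adjusted p = 0.0284), DCN (0.0408), GREM1 (0.0411) and CASP14 (0.0477) passed in limma on the same probe sets, while STOM and H3C11 did not. COL1A2 was represented by a probe set at 580 and 295 on the exposed arrays and at 5 and 29.8 on the SCC12 only arrays, the 5 being at the level of the bacterial controls (adjusted p = 0.0537), while another of its probe sets passed, at 723 against 7.35 (adjusted p = 0.0205). DCN, the collagen-binding proteoglycan decorin, was at 522 and 91.2 on exposed replicates 1 and 2 against 8.8 and 6.4 (adjusted p = 0.0687), and another of its probe sets passed (adjusted p = 0.0287). GREM1, a secreted antagonist of bone morphogenetic proteins, was at 625 and 108 on exposed replicates 1 and 2 against 8.7 and 11.8 (adjusted p = 0.0749). The SCC12 only signals of DCN and GREM1 lay at the level of the bacterial controls. CASP14, a caspase of the cornifying epidermis, STOM, a membrane scaffold protein, and H3C11, a replication-dependent histone H3 gene, had adjusted p of 0.0763, 0.0809 and 0.0909.

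**Figure D1:**
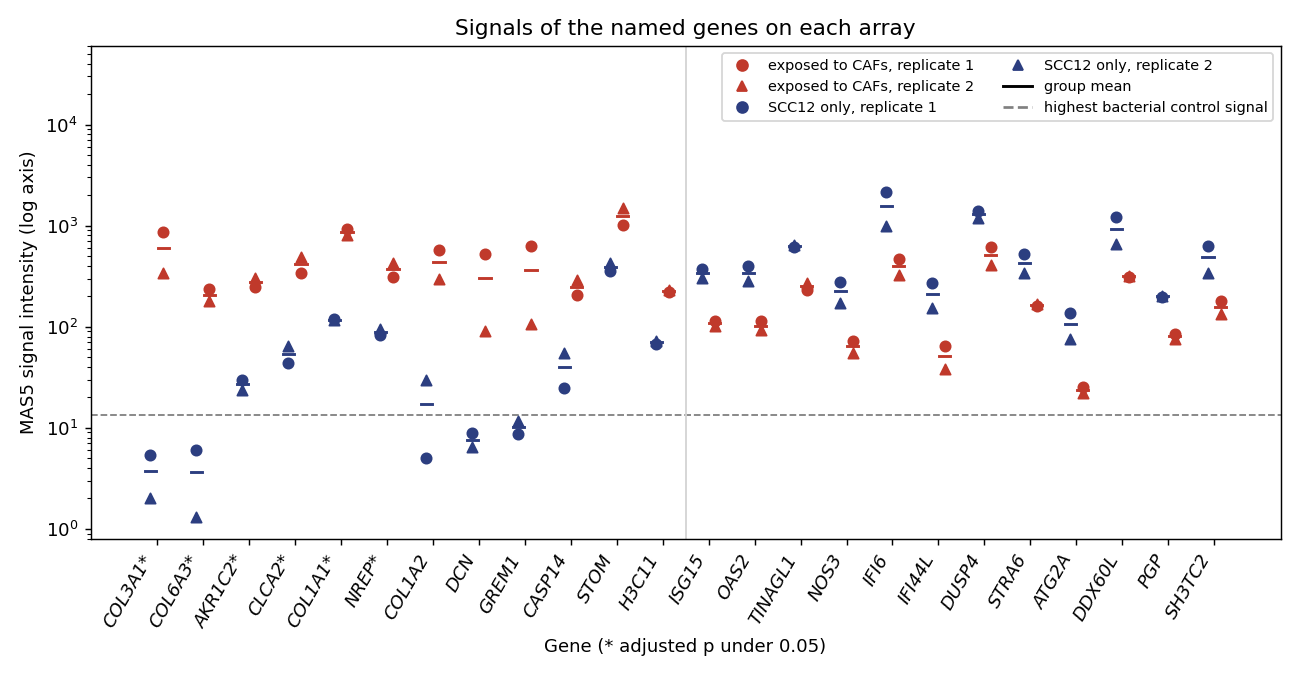
MAS5 signal intensity (log axis) of the 24 named genes on each of the 4 arrays, with points for arrays, short lines for group means and a dashed line at the highest bacterial control signal, 13.4. Genes with an asterisk passed an adjusted p of 0.05; COL3A1, COL6A3, DCN and GREM1 lie below the dashed line on both SCC12 only arrays.

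The fibroblast list as a whole was higher in exposed cells. Of its 22 measured members 19 had a positive difference, with a median of 1.26 on the log2 scale, also with genes at their bound. By adjusted p, 3 members rose over all probe sets and 12 adjusted over the list alone. Camera gave an adjusted p of 8.09e-12, and adjusted p = 0.686 with an estimated correlation. Members were not raised alike: TAGLN, ACTA2, FAP and TWIST1, also used as fibroblast markers, were near equal between groups, with FAP at 346 ± 25.5 against 295 ± 88.5 (SD, n = 2). LUM, a collagen-binding proteoglycan, at 95.8 against 1.65, and POSTN, a matrix protein, at 84.4 against 0.6, were not tested in the main fit because the filter removed them. Without the dim filter neither passed in limma. Endothelial, leukocyte and melanocyte markers had 2, 2 and 1 measured members and were not tested.

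Genes induced by interferon were lower in exposed cells. All 25 measured members of the interferon list had a negative difference, with a median of -1.02 on the log2 scale, which was -1.55 without SCC12 only replicate 2 and -0.852 without SCC12 only replicate 1. No member passed over all probe sets in the main fit, and 15 were lower adjusted over the list alone. Camera gave an adjusted p of 2.33e-14, and adjusted p = 0.686 with an estimated correlation. ISG15, a ubiquitin-like modifier, was at 108 ± 7.5 against 338 ± 47.4 (SD, n = 2, adjusted p = 0.0809), OAS2, an oligoadenylate synthetase, at 102 against 344 (adjusted p = 0.093), IFI6 at 469 and 322 against 2149 and 1001 on SCC12 only replicates 1 and 2 (adjusted p = 0.137) and IFI44L at 51.0 against 211 (adjusted p = 0.141).

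None of the 12 named lower genes passed in the main fit. With the replicate number as a block, described below, several did, among them IFI6, OAS2 and ISG15. Beside the 4 interferon genes, DUSP4, a phosphatase of MAP kinases, was at 512 against 1293, and NOS3, the endothelial nitric oxide synthase, at 64 against 226. TINAGL1, a secreted matrix protein, was at 252 against 631, STRA6, a retinol transporter, at 163 against 431, and ATG2A, an autophagy protein, at 23.8 against 107. DDX60L was at 315 against 931, PGP at 80.2 against 201 and SH3TC2 at 157 against 485. Their adjusted p lay between 0.116, for TINAGL1, and 0.194, for SH3TC2.

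The list of EGFR ligands and growth factors was lower, and it also holds receptors such as EGFR and binding proteins such as IGFBP3. Of its 16 measured members 15 had a negative difference (median -0.48 on the log2 scale) and 0 passed over all probe sets. Adjusted over the list alone, 2 were lower and 1 higher. Camera gave an adjusted p of 0.00114, and adjusted p = 0.686 with an estimated correlation. The EGFR ligand EREG was at 283 ± 59.7 against 597 ± 14.4 (SD, n = 2), NRG1, a ligand of ERBB receptors, at 77.2 against 178, and TGFA at 181 against 294. FGFBP1, a carrier of fibroblast growth factors, went the other way, at 600 against 331. The adjusted p was 0.0563 without exposed replicate 2 and 0.109 without SCC12 only replicate 1.

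Keratinocyte genes were higher as lists. Of 21 measured differentiation genes 15 had a positive difference (median 0.60), 0 passed over all probe sets and 4 were higher adjusted over the list alone, with a camera adjusted p of 0.017, and adjusted p = 0.686 with an estimated correlation. SPRR1B, a cornified envelope protein, was at 1218 ± 41.5 against 530 ± 41.3 (SD, n = 2). S100A8 and S100A9, subunits of calprotectin, were at 4822 against 1621 and at 956 against 382. PI3, the elastase inhibitor elafin, was at 1338 against 492. At an unadjusted p under 0.05 in limma 6 differentiation genes were higher and 2 lower, KLK6 (328.5 against 546) and ELF3 (592 against 904). Of 8 measured basal keratinocyte markers 7 had a positive difference (median 0.53), 0 passed over all probe sets and 3 were higher adjusted over the list alone, with a camera adjusted p of 0.0192, and adjusted p = 0.686 with an estimated correlation. The keratin KRT14 was at 624 and 2088 on the exposed arrays and at 90.2 and 650 on the others, KRT5 at 964 and 2322 against 290 and 848, DST at 986 against 405 and KRT15 at 257 against 149. The differentiation call was lost without the dim filter (adjusted p = 0.421), at the 60th percentile (0.0684), without exposed replicate 2 (0.0609) and without SCC12 only replicate 2 (0.112); the basal call was lost without exposed replicate 2 (0.0609) and without SCC12 only replicate 2 (0.0604).

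Mitotic, respiratory and ribosomal genes were slightly higher as lists by camera at its preset correlation. Of 27 measured mitosis genes 22 had a positive difference (median 0.43, camera adjusted p = 0.000415, and adjusted p = 0.737 with an estimated correlation), 0 passed over all probe sets and 2 were higher adjusted over the list alone. TOP2A, topoisomerase II alpha, was at 802 ± 16.5 against 421 ± 95 (SD, n = 2), BIRC5, survivin, at 816 against 426, BUB1 at 241 against 149 and CCNB2 at 407 against 265. Of 16 measured oxidative phosphorylation genes 14 had a positive difference (median 0.41, camera adjusted p = 0.00114, and adjusted p = 0.686 with an estimated correlation), and 0 passed over all probe sets or adjusted over the list alone. ATP5F1B, a subunit of ATP synthase, was at 1401 ± 27.7 against 824 ± 26.7 (SD, n = 2), NDUFB3 at 363 against 221, COX6C at 3682 against 2412 and NDUFA1 at 3140 against 2132. Of 14 measured ribosomal protein genes 12 had a positive difference (median 0.25, camera adjusted p = 0.0142, and adjusted p = 0.737 with an estimated correlation), and 0 passed over all probe sets or adjusted over the list alone. RPL11 was at 1558 against 776, RPS3 at 4675 against 2712, RPS14 at 4296 against 2801 and RPS6 at 3839 against 3030. The mitosis call was lost without exposed replicate 1 (adjusted p = 0.0919), the oxidative phosphorylation call without SCC12 only replicate 2 (0.112), and the ribosomal call without exposed replicate 2 (0.207) or SCC12 only replicate 2 (0.477).

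**Figure D2:**
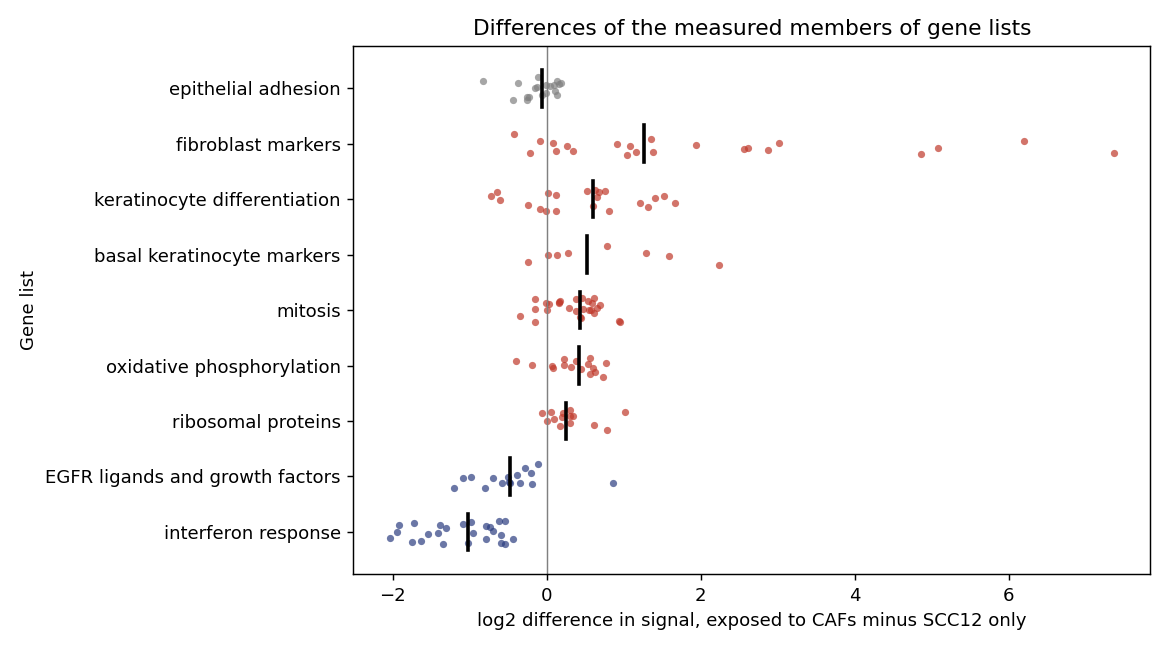
Log2 difference in signal, exposed to CAFs minus SCC12 only, of each measured member (points) of the 8 lists called by camera, in red where higher and blue where lower, and of the epithelial adhesion list in grey, which was not called; black lines are medians and the vertical scatter has no meaning. The interferon members all lie below 0, with a median of -1.02, and the epithelial adhesion median is -0.07.

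Of 29 lists tested 6 were higher and 2 lower. No list was called with an estimated correlation, where the smallest unadjusted p was 0.0494, or by the directional test of fry. In fry's test for change in either direction 2 lists passed, NRF2 targets and oxidative phosphorylation. Of 16 measured NRF2 targets 9 had a positive and 7 a negative difference, and 1, AKR1C2, passed over all probe sets. The camera adjusted p was 0.0641 for YAP targets, for MAPK feedback and immediate early genes, and for hypoxia and glycolysis, each of which passed under some alternatives. It was 0.074 for NRF2 targets, which passed with median centring (0.0277) and with the mean over probe sets (0.0442), 0.158 for antigen presentation and 0.191 for STAT3 targets. It was 0.246 for S phase and replication and for metallothioneins, 0.299 for cholesterol synthesis, 0.417 for mesenchymal transition, 0.425 for inflammatory NF-kB targets, 0.451 for TGF-beta targets, epithelial adhesion and fatty acid synthesis, and 0.508 for heat shock. It was 0.524 for p53 targets and for the unfolded protein and amino acid response, 0.75 for matrix proteases and inhibitors, 0.798 for Notch and Wnt targets, and 0.804 for integrins and laminins. Median, mean and test differed in sign for matrix proteases and for integrins and laminins.

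The GAPDH control probe sets differed by 0.32 ± 0.08 (3' minus 5', log2, SD, n = 2) on the exposed arrays and by 0.69 ± 0.02 on the SCC12 only arrays, with an exact permutation p of 0.333, the smallest that 2 arrays against 2 allow. The ACTB control probe sets differed by 2.84 ± 0.15 and 2.65 ± 0.44 (exact permutation p = 1).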

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

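Of 48 named genes, all kept their sign in the 764 alternative values computed. These genes were chosen for groups that did not overlap or for a small p, so this was largely fixed by the choice. Where groups do not overlap, leaving out an array or adding a constant cannot change the sign. The 6 that passed kept an adjusted p under 0.05 in 57 of 71 values that left out no array; the 14 losses were 6 without the intensity trend, 5 with the mean over probe sets, 2 with quantile normalization (COL6A3 and NREP) and 1 with the 60th percentile filter (NREP). The dim filter on the linear mean and camera with an intensity trend were chosen after seeing the data. Higher probe sets numbered 70 with median centring, 22 with 75th percentile scaling, 22 without the dim filter, 5 with the 60th percentile filter, 0 without the intensity trend (2411 at an unadjusted p under 0.05), 31 at an adjusted p under 0.10 and 7 with 1 probe set per gene, and lower probe sets 1 with median centring and 2 at an adjusted p under 0.10. Without 1 array, where the lone array is taken to vary like the other group, they numbered 39 to 137 higher and 3 to 103 lower. Over the 36 combinations of scaling, constant and filter, 3 to 95 were higher and 0 to 18 lower without the block, and 58 to 1150 higher and 25 to 737 lower with it. The cause was not tested, except that a stricter filter tests fewer probe sets.

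The labels do not say whether a replicate number marks a shared day, and 2 pairs are too few to tell. With the number as a block 644 probe sets were higher and 548 lower, all 13 main calls among them, and 39 of the 48 named genes passed, 14 of them lower. Deviations of same-numbered arrays correlated at 0.293 across probe sets. Parting the arrays by number called 0 probe sets in limma, with 2680 at an unadjusted p under 0.05, close to the 2971 of the real groups, while the crossed split called 0, with 209.

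Lists called higher numbered 0 with an estimated correlation and 0 with fry, and 2 to 8 without 1 array. Lists called lower numbered 4 with quantile normalization, 4 with 16 added, 4 with 64 added, 4 with the 60th percentile filter, 4 with the mean over probe sets, 4 with camera's intensity trend (7 higher), 0 with an estimated correlation, 0 with fry, and 1 to 4 without 1 array. Where 4 were lower, those gained were YAP targets (adjusted p = 0.0385 with quantile normalization) and MAPK feedback and immediate early genes (0.0388); MAPK also passed with median centring (0.0451). Hypoxia and glycolysis passed with 16 added (0.0466), 64 added (0.0368), the mean over probe sets (0.0456) and camera's intensity trend (0.046), and NRF2 targets with median centring (0.0277) and the mean over probe sets (0.0442). Antigen presentation passed without SCC12 only replicate 2 (0.0148, lower) and mesenchymal transition without exposed replicate 2 (0.0352, higher). The adjusted p of the fibroblast list was 0.686 with an estimated correlation and 0.188 with fry, and of the interferon list 0.686 and 0.317; each other alternative kept both calls. The mean correlation within groups was 0.908 without the dim filter.

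Lists that were not called changed sign. With the 60th percentile filter these were inflammatory NF-kB targets (adjusted p = 0.878), TGF-beta targets (0.992), p53 targets (0.752), and Notch and Wnt targets (0.968, and 0.918 with the filter on the linear mean). Matrix proteases changed sign with median centring (0.91) and integrins and laminins with the mean over probe sets (0.753). Leaving out 1 array also changed the sign of lists, with adjusted p over the 4 arrays from 0.000975 (higher, without exposed replicate 2) to 0.695 (lower, without SCC12 only replicate 2) for inflammatory NF-kB targets, 0.168 to 0.905 for epithelial adhesion (0.894 where its sign changed), 0.0563 to 0.843 for matrix proteases, and 0.409 to 0.878 for integrins and laminins. The range was 0.000243 (higher, without SCC12 only replicate 1) to 0.859 (lower, without SCC12 only replicate 2) for hypoxia and glycolysis, 0.346 to 0.977 for fatty acid synthesis, 0.154 to 0.859 for heat shock, and 0.695 to 0.964 for Notch and Wnt targets. The cause was not tested.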

Other observations

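The tests of explanations given here were chosen after the result was seen. MMP3, CXCL6 and CXCL5 were picked after their values were seen, for the gap between the exposed arrays. MMP3, stromelysin, was at 1163 and 43.7 on the exposed arrays and at 30.9 and 36.2 on the SCC12 only arrays, the chemokine CXCL6 at 453 and 64.9 against 2.2 and 21.1, and the chemokine CXCL5 at 332 and 33.4 against 16.1 and 18.4. Their adjusted p was 0.495, 0.226 and 0.374. AKR1C1, a close relative of AKR1C2, was at 288 ± 111 against 59.95 ± 37.3 (SD, n = 2, adjusted p = 0.164); probes of such paralogs can share transcripts.

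Fibroblast genes were higher in the exposed arrays. Noise of signals near 0 would not keep the calls when 64 is added before the logarithm, yet 12 of the 13 called probe sets were kept. The 13 also hold AKR1C2, CLCA2, NREP and the unnamed probe set, whose SCC12 only signals lay above 13.4, so that count alone says little. COL3A1 and COL6A3, at background on both SCC12 only arrays, kept their calls in limma with 64 added (adjusted p = 0.0075 and 0.00468). RNA carried over from the CAFs and induction in the tumour cells both stay open, and no CAF array was analysed here. Of the 7 listed genes at background on both SCC12 only arrays, 6, or 85.7%, were above it on both exposed arrays. All 6 were higher on exposed replicate 1 than on replicate 2, by a median log2 of 1.18 (SD 0.759 over these genes). Over tested probe sets that median was -0.0573. VIM, abundant in fibroblasts, exceeded both SCC12 only arrays on exposed replicate 1 alone, at 258 and 70.5 against 86.1 and 87.7. TAGLN, at 30.9 against 29.6, and ACTA2, at 62.8 against 50.5, were near equal between groups. The baseline of VIM, TAGLN and ACTA2 in SCC12 could hide a small share. A shift of the SCC12 cells towards a mesenchymal state would lower the epithelial adhesion list and raise the mesenchymal transition list. Neither was called by camera (adjusted p = 0.451 and 0.417), with medians of -0.07 (-0.0679) and 0.08, over members that go both ways. Of 14 measured mesenchymal members 8 had a positive and 6 a negative difference. These lists gave no sign of a broad shift, but a shift in a few genes stays open.

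Interferon genes were lower in the exposed arrays. The median log2 difference of -1.02 was -0.852 without SCC12 only replicate 1 and -1.55 without SCC12 only replicate 2, the ends of the range over the 4 arrays, so its size depends on the SCC12 only array used while its sign does not rest on 1 array alone. Under another scaling it was at most -0.916. The scalings tried moved the genes little, with a median over tested probe sets from -0.030 without scaling to 0.071 with median centring. This check could therefore hardly have come out otherwise. Dilution by RNA of other cells would lower the epithelial adhesion genes as much, yet their median lay 0.95 above that of the interferon list, against an SD of 0.255 over its members. An effect of the exposure stays open as a hypothesis, as do culture differences such as the gel, which were not tested. The exposed samples held only tumour cells that had not invaded, and the design cannot separate this selection from the exposure.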
